A study of Rattus norvegicus with 6 samples.

How the data were processed

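Total RNA from the renal cortex of 6 male rats was labelled with the dye Cy3 and hybridised to Agilent single-colour arrays, 1 array per animal, per the labels' protocols. The labels give 3 biological replicates per group, with water or potassium bromate given over 4 weeks (100 mg/kg/day) to rats bought at 5 weeks of age. The arrays were read with Agilent Feature Extraction 10.7, per the submitters' processing notes, and are annotated on the rat genome build rn4, per the file headers. Feature Extraction wrote a processed signal per spot, an intensity that is background-subtracted and detrended but not scaled between arrays, per the file headers. It also wrote flags for spots well above background, saturated spots and outliers. The deposited value table of the authors holds a ratio on a linear scale. Set against the scanner values, each of its columns equalled the processed signal divided by that array's 75th percentile, to within 0.59% to 0.917% at the worst probe. It is not centred by gene, its direction is that of the signal, and none of these is stated in the labels. Its column medians were 0.1043, 0.1049 and 0.1031 for water replicates 1 to 3 and 0.1025, 0.1055 and 0.1026 for bromate replicates 1 to 3. Which software scaled the table is not given in the sources used here.

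Each array had 61537 probes besides 1439 control spots, and 36517, 38801 and 38506 probes on water replicates 1, 2 and 3 and 35621, 37536 and 38180 on bromate replicates 1, 2 and 3 were well above background. No array had a saturated probe, and 0 to 4 spots per array were outliers. Probes were named by the transcript accession in the scanner files, looked up in the reference gene table: 28206 probes (45.8%) had 1 symbol, none had several and 33331 had none, which leaves them unnamed here, not without a gene. The named probes held 15645 symbols. No reference genome of build rn4 was used, and no coordinates are given.

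The processed signal was put on the log2 scale and reduced by the log2 of each array's 75th percentile over its non-control probes. Control spots and outlier spots were left out. A probe entered when well above background on at least 3 of the 6 arrays, whatever the group, which 37783 probes did. Of several probes of a symbol, the one with the highest mean over all 6 arrays stood for the gene, and a probe without a symbol stood for itself, giving 27506 genes. The other probes of changed genes numbered 1613 for 1189 genes, of which 1547 went in the same direction and 66 in the opposite one. Tested one by one, 953 of them were called, 2 of these in the opposite direction, in 1 gene.

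Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with Benjamini-Hochberg adjustment over all genes tested, a threshold of 0.05 and, for the smaller counts, at least 2-fold. Slide was not in the model because 1 slide held 1 water array only, so a slide term takes that array out of the comparison. A gene not well above background on any array of 1 group is given as a bound: the mean of the brighter group over the mean, in the dimmer group, of the higher of the array's lowest signal well above background and the probe's own signal. List medians were the same to 2 decimals with such genes at their bound.

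The 27 gene lists were fixed before the data were examined, from general knowledge of rat kidney and of oxidising toxicants. Of 719 entries 674 were matched to a named probe by symbol and 2 by synonym, 43 had no named probe, and 627 were measured. Lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Counts are given over all genes tested and adjusted over the list alone. The genes named were also fixed by a rule before the data were examined: the 10 largest rises and falls with a symbol, at least 2-fold, without overlap between groups and well above background on all 3 arrays of the higher group, then up to 4 members with the largest change from each list (the brightest member where none was called), and 18 genes chosen in advance. Some of the genes that this rule names are not reported here. Genes outside that rule are said to have been chosen after their values were seen, as are 6 added lists and 16 gene families. The list of intercalated cell markers among these was trimmed to members of the collecting duct list after values had been seen.

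Alternatives were quantile normalization, the percentile over probes well above background on all arrays, normexp background correction (offset 50) with quantile normalization, the value table, no filter on dim probes, a filter on all 6 arrays, outlier spots kept, the mean of a gene's probes, each probe tested for itself, an intensity trend with robust variance, array weights, slide and replicate number as blocks, each array left out in turn and limma's treat at 1.2-fold. Normexp used the median spot intensity with the local background intensity, since the deposited scanner files hold no mean signal. The tests of genes and lists, not the steps before them, were tried on simulated data with the spread of the real arrays (27505 genes, 5 simulations of 200 changed genes). In these data 9.85% of changes of 0.5 on the log2 scale, 45.1% of changes of 1 and 79.1% of changes of 2 were called, and 3.89% of calls were false. Far more genes, 3979, were called in the real data, so the shares called there can differ from these. Of 5 simulated lists shifted by 0.5 on the log2 scale 5 were called, and of 130 unshifted lists 0 by camera. Those simulated genes vary independently, which those of an animal do not.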

Results

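Gene expression was measured in the renal cortex of 6 male Sprague-Dawley rats, 3 given water and 3 given potassium bromate at 100 mg/kg/day over 4 weeks. Potassium bromate is an oxidising compound that is toxic to the kidney. RNA of each animal was hybridised to 1 single-colour array with 61537 probes, of which 35621 to 38801 per array (57.9% to 63.1%) were well above background and 0 were saturated. Water replicate 1 was alone on its slide, and the other 5 arrays shared the other slide. Across genes, which are not independent replicates, arrays correlated at 0.983 to 0.992 within the water group, 0.988 to 0.991 within the bromate group and 0.966 to 0.978 between the groups. The first principal component held 53.8% of the variance and separated the groups, the second (17.6%) set water replicate 1 apart and the third (13.03%) set bromate replicate 1 apart. Levels below are log2 signals relative to the 75th percentile of the same array, as mean ± SD, and differences are bromate minus water ± standard error, with n = 3 per group throughout. The number of arrays limits the precision of every value.

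The comparison asked which genes of the renal cortex changed under potassium bromate. Genes of tubule injury, of immediate early transcription and of the NRF2 and p53 responses were higher as lists, and markers of the proximal tubule, the thick ascending limb, the distal tubule and the collecting duct were lower. With an estimated correlation between list members none of the 27 lists was called (lowest adjusted p = 0.111). The largest rise was that of Havcr1, which encodes kidney injury molecule 1 of damaged proximal tubule cells, from -4.81 ± 0.72 to 3.30 ± 0.13 (276-fold, log2 difference 8.11 ± 0.35). Spp1, which encodes osteopontin, rose 28.3-fold and the fibrinogen gene Fgb 25.03-fold. Gp2, which encodes a glycoprotein related to uromodulin, was 52.9-fold lower, the anion exchanger gene Slc26a4 of intercalated cells 44.3-fold lower and the growth factor gene Egf 34.1-fold lower. Of 27506 genes tested (1 probe each, 11572 with a gene symbol and 15934 without), 1891 rose and 2088 fell by limma with Benjamini-Hochberg adjustment, together 14.5%. At least 2-fold, 610 rose and 538 fell. With a symbol, 995 rose and 964 fell, of which 348 and 262 at least 2-fold.

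All 3979 changed genes had no overlap between the 3 water and 3 bromate values, as did 11289 of all genes tested (41.0%, against 10% by chance). With slide as a block, which leaves water replicate 1 out of the comparison, 1495 genes rose and 1835 fell, as among the 5 arrays of the other slide alone. The counts of genes that rose and fell were 594 and 530 without water replicate 2, 746 and 738 without water replicate 3, 654 and 598 without bromate replicate 2 and 839 and 918 without bromate replicate 3. Without bromate replicate 1, 1105 genes fell. Genes at least 2-fold lower numbered 310 without water replicate 2 and 327 without bromate replicate 2, and those at least 2-fold higher 406 without water replicate 2. The median difference over all genes was -0.02.

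The 10 largest rises and the 10 largest falls among genes with a symbol followed from a rule set before the data were examined. Besides Havcr1, Spp1 and Fgb, the largest rises were in Il24 (at least 37.2-fold), the transcription factor gene Fosl1 (at least 19.03-fold), the transglutaminase gene Tgm1 (at least 19.1-fold), Serpina3n (45.03-fold), the fibrinogen gene Fgg (at least 15.02-fold), Reg3b (at least 6.13-fold) and Gpnmb (23.5-fold). A bound stands where a gene was not well above background on any array of its lower group. Havcr1 was well above background on 2 of the 3 water arrays. The log2 difference of Serpina3n was 5.49 ± 1.19, and its call did not hold on leaving out any 1 array, with adjusted p up to 0.103. The Serpina3n log2 fold change was 4.78 without water replicate 2, 6.27 without water replicate 3, 6.10 without bromate replicate 1 and 4.33 without bromate replicate 2. Besides Gp2, Slc26a4 and Egf, the largest falls included the insulin receptor-related gene Insrr (at least 14.4-fold), the glucagon receptor gene Gcgr (18.2-fold), Cga (at least 3.54-fold), Tmem163 (at least 4.01-fold), Lrrc66 (at least 2.96-fold) and the kinase gene Mylk3 (8.85-fold). Adjusted p for these genes ran from 0.000122 for Spp1 to 0.0349 for Serpina3n. In filling the 10 places, 2 rises and 16 falls of probes or genes without a proper symbol were passed over. Changed genes held by a bound numbered 83 with a dim water group and 134 with a dim bromate group.

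**Figure D1:**
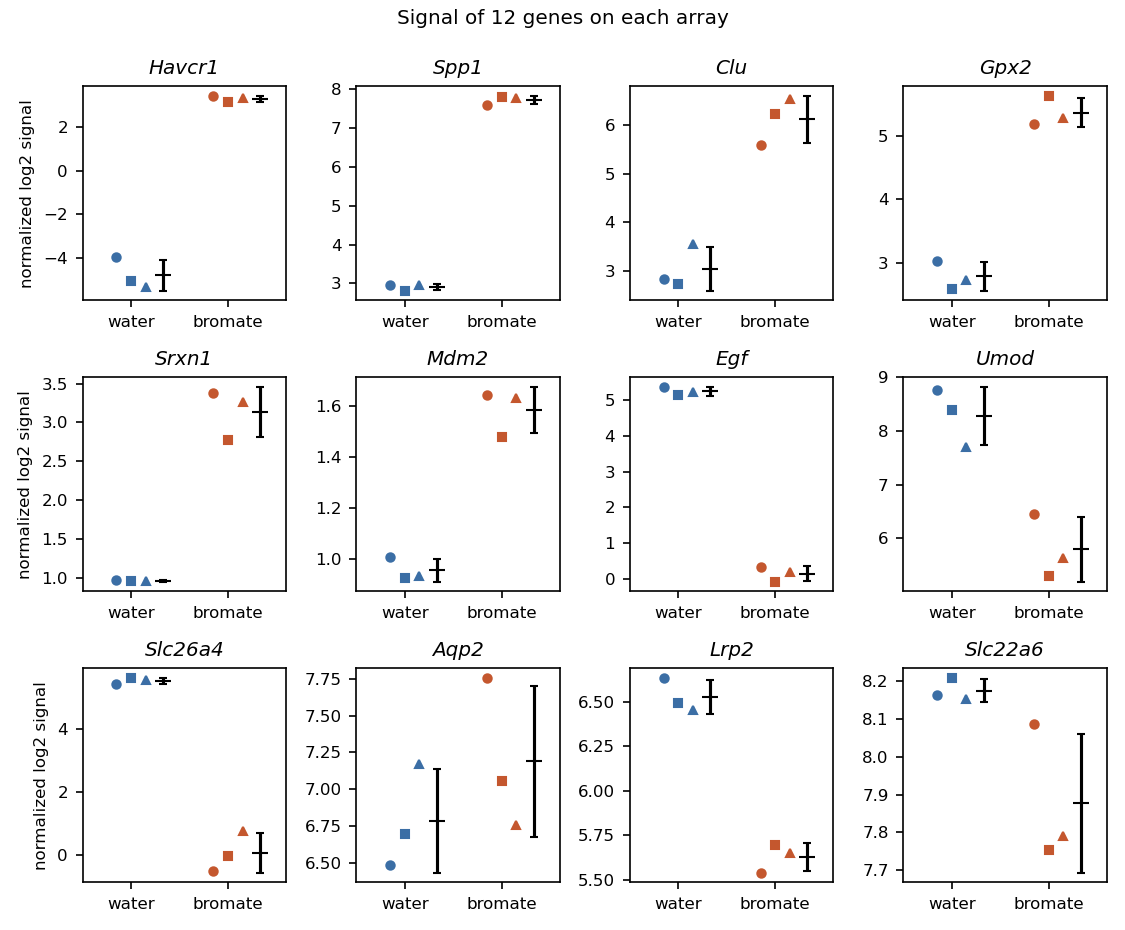
Levels of single genes on each of the 6 arrays (log2 relative to the array's 75th percentile, own vertical scale per panel), with circle, square and triangle for replicates 1, 2 and 3 and bars for the mean ± SD of each group. Havcr1 lies at -4.81 ± 0.72 in the water group and 3.30 ± 0.13 in the bromate group, and Egf at 5.25 ± 0.12 and 0.15 ± 0.21.

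The 27 gene lists, fixed before the data were examined, were tested against all other genes with camera at its preset correlation. In all, 9 lists were higher under bromate, 9 were lower and 9 were not called. With an estimated correlation 0 lists were called by camera (smallest adjusted p = 0.111, and 4 lists at an unadjusted p under 0.05), and the self-contained test fry, which asks whether a list's genes move one way and does not compare them with other genes, called 17. The p53 list (-0.00741) and the thick ascending limb and distal tubule list (-0.0223) had estimated correlations below the preset 0.01. Both still lost their call, so a higher correlation between members was not what ended the calls of those lists. In the other lists called at the preset, estimated correlations ran from 0.0799 for tubule injury markers to 0.749 for cell division genes. All of these lay above the preset, so the p-values of camera at the preset rest on a lower correlation than estimated there. Among the lists called by camera, fry did not call cell division (adjusted p = 0.142), macrophage (0.211) and lymphocyte genes (0.142), and it called base excision repair (0.000842) and renin-angiotensin genes (0.0219), which camera did not. Camera at the preset correlation also called up to 14 lists when the 6 arrays were split into other groups of 3. Each of those splits has arrays of both treatments on both sides and keeps part of the treatment difference. The 14 lists are therefore not a rate of false calls, but these splits cannot tell that remaining difference from false calls either.

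**Figure D2:**
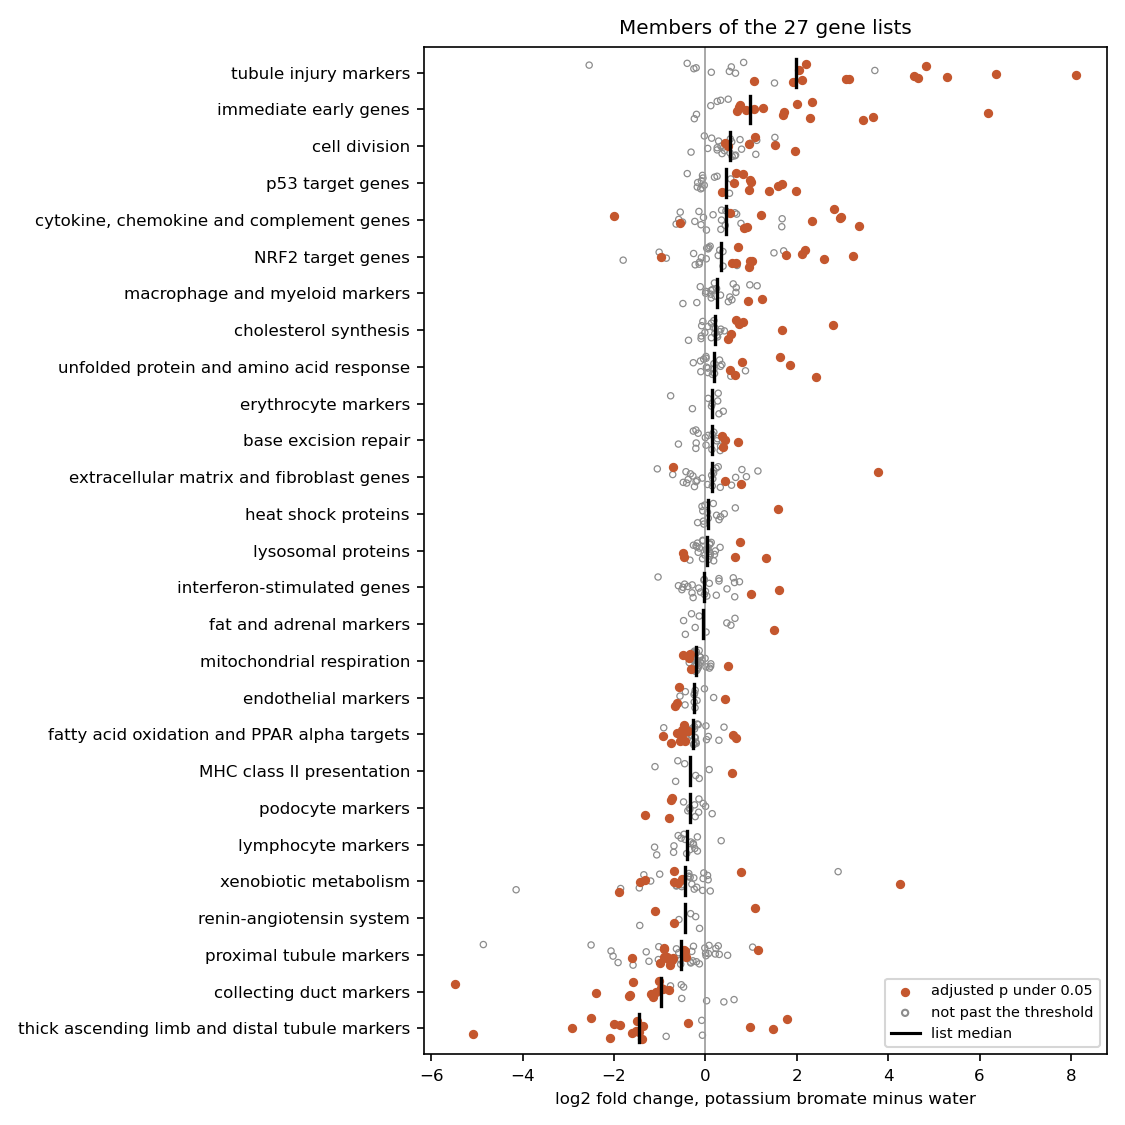
Log2 differences (bromate minus water) of the measured members of each gene list, with 1 point per gene and a mark at the list median. Medians run from -1.46 for thick ascending limb and distal tubule markers to 1.98 for tubule injury markers.

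Injury markers of the tubule were higher as a group. Of 24 measured members 13 rose, 0 fell and 11 did not pass, and adjusted over the list alone 18 rose. Besides Havcr1, Il24, Spp1, Gpnmb and the fibrinogen genes, these included Clu, which encodes the chaperone clusterin (8.47-fold, 3.08 ± 0.32, adjusted p = 0.00545), and, chosen after their values were seen, Timp1, an inhibitor of matrix proteases (4.59-fold), and the hyaluronan receptor gene Cd44 (4.3-fold). The median member was 1.98 higher (camera adjusted p = 4.12e-12; adjusted p = 0.111 with an estimated correlation), and 1.99 with slide as a block. Lcn2, which encodes the lipocalin NGAL and was named in advance, had a difference of 3.71 ± 1.17 that did not pass (adjusted p = 0.087), with bromate values of -1.14, 1.86 and 2.17 and water values of -1.60, -2.00 and -4.64.

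Immediate early genes, mostly of transcription factors that are switched on quickly by a stimulus, were higher together. Of 20 members 14 rose, 0 fell and 6 did not pass, with the same counts adjusted over the list alone. Beside Fosl1 stood Egr2 (at least 4.38-fold, adjusted p = 0.00566), the stress-response factor gene Atf3 (10.8-fold, 3.44 ± 0.39) and Myc (5.02-fold, 2.33 ± 0.20). The list median was 0.97, and 1.01 with slide as a block (camera adjusted p = 5.04e-09; adjusted p = 0.179 with an estimated correlation). The count that rose was 8 without water replicate 2 and 9 without bromate replicate 2.

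Genes that answer to NRF2, the factor of the oxidative stress response, and to p53, the factor of the DNA damage response, were higher as lists. Of 32 NRF2 targets 11 rose, 1 fell and 20 did not pass (14 and 2 adjusted over the list alone). The glutathione peroxidase gene Gpx2 rose 5.997-fold (2.58 ± 0.17), the sulfiredoxin gene Srxn1 4.504-fold (2.17 ± 0.17), the haem oxygenase gene Hmox1 4.34-fold (2.12 ± 0.24) and the glutathione transferase gene Gstm1 9.38-fold (3.23 ± 0.72, adjusted p up to 0.106 on leaving out any 1 array other than bromate replicate 3). The Gstm1 log2 fold change was 3.92 without bromate replicate 3. The 1 that fell, named after its value was seen, was the glutathione transferase gene Gsta5 (1.95-fold, adjusted p up to 0.129 on leaving out any 1 array other than water replicate 3). Nqo1, a quinone reductase gene, did not pass (2.83-fold, adjusted p = 0.0568), while its second probe did (1.75, adjusted p = 0.0331). Without bromate replicate 2 the Nqo1 log2 fold change was 1.91 and passed (adjusted p = 0.0318). Gclc, which encodes the catalytic subunit of glutamate-cysteine ligase, had water values of 8.02, 6.18 and 3.99 and a difference of -1.80 ± 1.04 (adjusted p = 0.284). Across the same 3 water arrays, straight-tubule genes averaged 4.08, 2.42 and 1.00. The NRF2 list had a median of 0.35 (camera adjusted p = 0.00046; adjusted p = 0.371 with an estimated correlation), and 0.36 with slide as a block. Its count that rose was 5 without water replicate 2 or 3, 7 without bromate replicate 1 or 2 and 6 without bromate replicate 3, and the count that fell was 0 by limma on leaving out any 1 array other than water replicate 3.

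Of 24 p53 targets 11 rose, 0 fell and 13 did not pass, with the same counts adjusted over the list alone. Bbc3, which encodes the apoptosis inducer PUMA, rose 2.64-fold (1.40 ± 0.14), the death receptor gene Fas 3.01-fold (1.59 ± 0.17), the antiproliferative gene Btg2 3.94-fold (adjusted p = 0.0517 without water replicate 2) and Gdf15 3.19-fold (adjusted p up to 0.0639 without water replicate 2 or bromate replicate 2 or 3). Mdm2, the p53 ubiquitin ligase gene, rose 1.55-fold (adjusted p = 0.051 without water replicate 2) and cyclin G1 (Ccng1) 1.95-fold (adjusted p up to 0.0553 without bromate replicate 2 or 3, and 0.195 with the mean of its probes). The probes of Cdkn1a, which encodes the cell cycle inhibitor p21, disagreed. The brightest gave -0.10 ± 0.16 (adjusted p = 0.698), another 2.70 ± 0.28 (adjusted p = 0.0054) and the third, the dimmest, 1.86 ± 1.09 (adjusted p = 0.286). The p53 list had a median of 0.45, and 0.36 with slide as a block (camera adjusted p = 0.000498; adjusted p = 0.129 with an estimated correlation). Its count that rose was 5 without water replicate 2 or bromate replicate 2 and 6 without bromate replicate 3.

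The base excision repair list, whose enzymes remove oxidised bases from DNA, was not called (median 0.15, 0.16 with slide as a block, camera adjusted p = 0.0805, adjusted p = 0.362 with an estimated correlation). Of 20 members 4 rose, 0 fell and 16 did not pass, and adjusted over the list alone 6 rose and 1 fell. Ogg1, the glycosylase gene for 8-oxoguanine, rose 1.34-fold (0.43 ± 0.08, adjusted p up to 0.0888 on leaving out any 1 array other than water replicate 1), as did the glycosylase gene Nthl1 (1.64-fold, adjusted p up to 0.0562 without water replicate 2 or bromate replicate 2), Fen1 (1.31-fold, adjusted p up to 0.096 on leaving out any 1 array other than water replicate 1) and Pcna (1.29-fold, adjusted p up to 0.138 on leaving out any 1 array other than bromate replicate 1). The count that rose was 0 without water replicate 2 or bromate replicate 2, 1 without water replicate 3 or bromate replicate 3 and 2 without bromate replicate 1, and 1 fell without water replicate 1.

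Cell division genes were higher in bromate replicates 2 and 3. Their list mean was 0.05 and -0.07 on those arrays, against -1.08 on bromate replicate 1 and -0.86, -0.95 and -1.20 on the water arrays. Of 29 members 6 rose, 0 fell and 23 did not pass, and adjusted over the list alone 7 rose. Cyclin E1 (Ccne1) rose 3.86-fold (1.95 ± 0.19), the replication licensing genes Mcm3 2.86-fold (1.52 ± 0.19) and Mcm4 1.93-fold (0.95 ± 0.12), and the spindle gene Tpx2 2.11-fold (adjusted p up to 0.0893 on leaving out any 1 array other than bromate replicate 1). Mki67, which encodes the proliferation antigen Ki-67, did not pass (0.58 ± 0.39, adjusted p = 0.358). Without bromate replicate 1 the Mki67 log2 fold change was 1.03 and passed (adjusted p = 0.025). The median was 0.55, and 0.67 with slide as a block (camera adjusted p = 4.44e-05; adjusted p = 0.493 with an estimated correlation). The count that rose was 3 on leaving out any 1 array other than bromate replicate 1 and 16 without bromate replicate 1.

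Proximal tubule markers were lower. Of 49 members 1 rose, 14 fell and 34 did not pass, and adjusted over the list alone 19 fell. Kap, an androgen-regulated gene of the proximal tubule, was 3.06-fold lower (-1.61 ± 0.27, adjusted p up to 0.0603 without water replicate 2 or bromate replicate 2), the aminopeptidase gene Anpep 1.99-fold lower (adjusted p up to 0.0812 without water replicate 3 or bromate replicate 1 or 2), the glucose carrier gene Slc5a2 1.89-fold lower (-0.92 ± 0.12) and the endocytic receptor gene Lrp2 1.86-fold lower (-0.90 ± 0.09). The 1 member that rose was the glucose carrier gene Slc2a2 (2.23-fold, 1.16 ± 0.13), and the organic anion carrier gene Slc22a6 did not pass (-0.30 ± 0.11, adjusted p = 0.128). The median was -0.54, and -0.49 with slide as a block (camera adjusted p = 1.96e-05; adjusted p = 0.362 with an estimated correlation). The count that fell was 8 without water replicate 2 or 3 and 7 without bromate replicate 2.

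Genes of the straight part of the proximal tubule, a list drawn up after the data were seen, spread widely over the water arrays. Their mean over 13 genes was 4.08, 2.42 and 1.00 on water replicates 1, 2 and 3 and 1.64, 0.27 and 1.53 on bromate replicates 1, 2 and 3, and 0 of the 13 were called by limma (4 at an unadjusted p under 0.05). The amino acid carrier gene Slc7a13, an example chosen after its values were seen, had water values of 7.61, 4.83 and 2.54 and a difference of -3.96 ± 1.38 (adjusted p = 0.109). A list of 13 genes of the convoluted part, also drawn up then, had means of 5.62, 5.62 and 5.74 on the water arrays and 5.48, 5.36 and 5.37 on the bromate arrays, with 1 that rose and 5 that fell. With the straight-tubule mean as a covariate, chosen after the data were seen, 734 of all genes rose and 739 fell, against 1891 and 2088 without it.

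**Figure D3:**
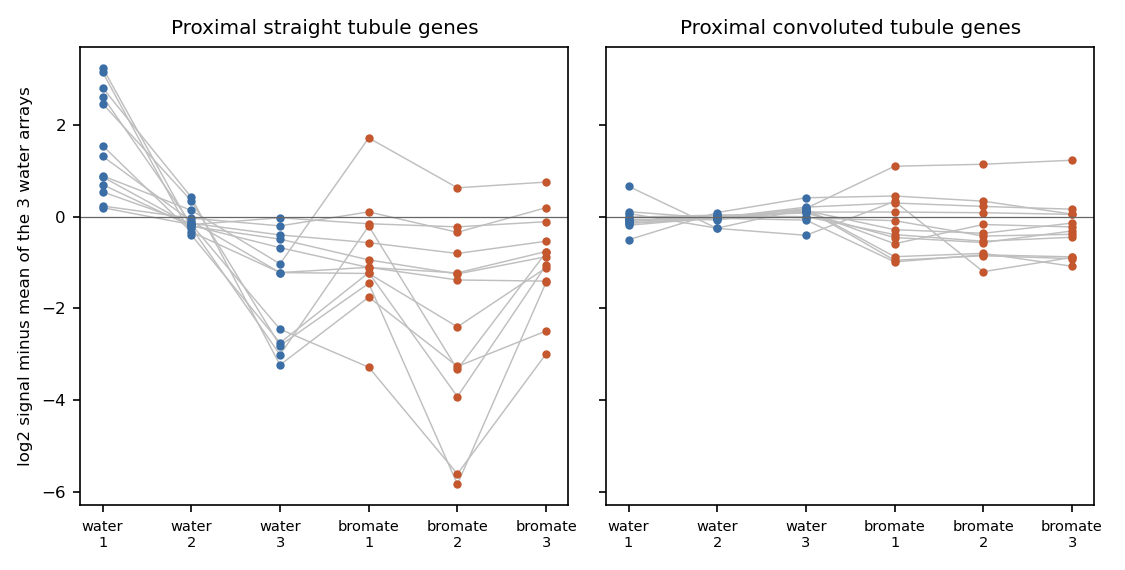
Straight-tubule and convoluted-tubule genes on each of the 6 arrays (log2 scale), with grey lines joining the values of 1 gene. As levels relative to the array's 75th percentile, the straight-tubule list mean ran from 4.08 on water replicate 1 to 0.27 on bromate replicate 2. On the same scale the convoluted-tubule list mean stayed between 5.36 and 5.74.

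Markers of the thick ascending limb and distal tubule had the lowest list median. Of 19 members 13 fell, 3 rose and 3 did not pass, and adjusted over the list alone 14 fell and 3 rose. After Egf (-5.09 ± 0.14) the largest falls were in the phosphatase inhibitor gene Ppp1r1a (7.54-fold, -2.91 ± 0.16), in Umod, which encodes uromodulin (5.65-fold, -2.50 ± 0.39, adjusted p up to 0.0625 without water replicate 2 or bromate replicate 2 or 3), and in the calcium-binding protein gene Calb1 (4.27-fold, -2.09 ± 0.37, adjusted p up to 0.0779 on leaving out any 1 array other than water replicate 1). The 3 that rose, named after their values were seen, were the calcium channel gene Trpv5 (3.43-fold, adjusted p up to 0.0931 on leaving out any 1 array other than water replicate 3), the kininogen gene Kng1 (2.79-fold, adjusted p up to 0.079 without water replicate 2 or 3) and the prostaglandin receptor gene Ptger3 (1.98-fold). The claudin gene Cldn19, also chosen then, had a difference of -0.07 ± 0.24 (adjusted p = 0.871). The median was -1.46, and -1.45 with slide as a block (camera adjusted p = 1.72e-05; adjusted p = 0.111 with an estimated correlation). The count that fell was 6 without water replicate 2, 7 without bromate replicate 2 and 8 without bromate replicate 3, and the count that rose was 1 without water replicate 2.

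Collecting duct markers fell without an exception among those called. Of 19 members 12 fell, 0 rose and 7 did not pass, and adjusted over the list alone 13 fell. Slc26a4 was followed by the transcription factor gene Elf5 (5.297-fold, adjusted p = 0.0554 without water replicate 2) and by the proton pump subunit genes Atp6v1b1 (3.19-fold, -1.67 ± 0.15) and Atp6v1g3 (3.13-fold, -1.65 ± 0.17). Elf5 was well above background on 3 water arrays and 1 bromate array. The water channel gene Aqp2 of principal cells did not pass (0.40 ± 0.30, adjusted p = 0.399). The median was -0.98, and -1.11 with slide as a block (camera adjusted p = 2.31e-07; adjusted p = 0.362 with an estimated correlation). The count that fell was 7 without water replicate 2.

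Podocyte and endothelial markers were lower by smaller amounts. Of 15 podocyte markers 4 fell, 0 rose and 11 did not pass (6 fell adjusted over the list alone), namely the collagen gene Col4a4 (2.49-fold, adjusted p up to 0.0603 without water replicate 2 or 3), Cdkn1c (1.73-fold, adjusted p up to 0.114 without water replicate 2 or 3 or bromate replicate 2 or 3), Thsd7a (1.69-fold, adjusted p up to 0.0876 on leaving out any 1 array other than bromate replicate 1) and Wt1 (1.65-fold, adjusted p up to 0.138 without water replicate 2 or 3 or bromate replicate 2 or 3). Of 15 endothelial markers 3 fell, 1 rose and 11 did not pass (4 and 1 adjusted over the list alone). The claudin gene Cldn5 was 1.59-fold lower (adjusted p up to 0.0838 without water replicate 2 or bromate replicate 1, 2 or 3), Emcn 1.55-fold lower (adjusted p up to 0.0684 without water replicate 2 or 3 or bromate replicate 2 or 3) and Tie1 1.498-fold lower (adjusted p = 0.0521 without bromate replicate 2), while Esam rose 1.35-fold (adjusted p up to 0.117 on leaving out any 1 array). Camera's adjusted p was 0.00403 and 0.0127 for the podocyte and endothelial lists (adjusted p = 0.362 for both with an estimated correlation). Medians were -0.34 and -0.25, and -0.36 and -0.35 with slide as a block. The podocyte count that fell was 0 without water replicate 2 or 3 and 1 without bromate replicate 2 or 3, the endothelial count that fell 1 without water replicate 2 or bromate replicate 3 and 0 without bromate replicate 2, and the endothelial count that rose 0 by limma on leaving out any 1 array.

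Cytokine, chemokine and complement genes were higher as a list. Of 32 members 9 rose, 2 fell and 21 did not pass (10 and 3 adjusted over the list alone). The chemokine gene Ccl20 rose 10.3-fold (adjusted p up to 0.0661 without water replicate 2 or 3), Cxcl2 at least 2.22-fold, Cxcl10 7.699-fold (adjusted p = 0.0533 without water replicate 2) and the TWEAK receptor gene Tnfrsf12a 6.99-fold (2.81 ± 0.31). The 2 that fell, named after their values were seen, were the T cell attracting chemokine gene Cxcl9 (at least 3.32-fold) and the complement inhibitor gene Cd55 (1.48-fold, adjusted p up to 0.0763 without water replicate 2 or 3 or bromate replicate 1 or 3). The median was 0.44, and 0.55 with slide as a block (camera adjusted p = 0.00403; adjusted p = 0.362 with an estimated correlation). The count that rose was 4 without water replicate 2 and 5 without water replicate 3, and the count that fell 1 without water replicate 2 or 3 or bromate replicate 1 or 3.

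Macrophage and myeloid markers were higher as a list and lymphocyte markers lower. Of 23 macrophage markers 2 rose, 0 fell and 21 did not pass, with the same counts adjusted over the list alone. The 2 were the lipopolysaccharide co-receptor gene Cd14 (2.35-fold, 1.23 ± 0.12) and the complement gene C1qb (1.91-fold, adjusted p up to 0.108 on leaving out any 1 array other than bromate replicate 1). As with cell division genes, bromate replicate 1 stood apart: the macrophage list mean was 0.66 there, 1.199 and 1.17 on bromate replicates 2 and 3 and 0.60, 0.62 and 0.69 on the water arrays. Ptprc, the pan-leukocyte antigen gene, did not pass (-0.11 ± 0.21, adjusted p = 0.742). Of 17 lymphocyte markers 0 rose and 0 fell by limma, also adjusted over the list alone (0 higher and 3 lower at an unadjusted p under 0.05), and the brightest, the T cell receptor gene Cd3d, had a difference of -0.17 ± 0.10 (adjusted p = 0.265). The macrophage median was 0.24 (0.23 with slide as a block, camera adjusted p = 0.00403, adjusted p = 0.527 with an estimated correlation) and the lymphocyte median -0.41 (-0.40, 0.0169 and adjusted p = 0.493 with an estimated correlation). The lymphocyte call ended without bromate replicate 1 (adjusted p = 0.118) and with array weights (0.0582), and the macrophage count that rose was 1 without water replicate 1, 2 or 3 or bromate replicate 3 and 5 without bromate replicate 1.

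Genes of fatty acid oxidation, mitochondrial respiration and xenobiotic metabolism were lower. Of 34 fatty acid oxidation genes and PPAR alpha targets 9 fell, 2 rose and 23 did not pass (16 and 2 adjusted over the list alone). The fatty acid hydroxylase gene Cyp4a1 was 1.897-fold lower (-0.92 ± 0.09), the dehydrogenase gene Acadm 1.67-fold lower (adjusted p up to 0.0892 on leaving out any 1 array other than bromate replicate 1) and Ech1 1.54-fold lower (adjusted p up to 0.0612 without water replicate 3 or bromate replicate 2 or 3). The 2 that rose were Angptl4, which encodes a lipase inhibitor (1.59-fold, adjusted p up to 0.0782 on leaving out any 1 array), and, named after its value was seen, Cyp4a3 (1.52-fold, adjusted p up to 0.0781 without water replicate 1, 2 or 3 or bromate replicate 3). Of 35 respiration genes 4 fell, 1 rose and 30 did not pass (6 and 1 adjusted over the list alone). Pdha1, of the pyruvate dehydrogenase complex, was 1.41-fold lower (adjusted p up to 0.0776 on leaving out any 1 array other than water replicate 1), Ndufs3 1.28-fold lower (adjusted p up to 0.124 on leaving out any 1 array) and Sdhb 1.27-fold lower (adjusted p up to 0.117 on leaving out any 1 array), while the citrate synthase gene Cs rose 1.42-fold (adjusted p up to 0.065 without water replicate 2 or 3 or bromate replicate 2 or 3). Medians were -0.27 and -0.20, and -0.28 and -0.18 with slide as a block. Camera's adjusted p was 0.00038 and 0.000646 (adjusted p = 0.362 and 0.491 with an estimated correlation). The fatty acid count that fell was 5 without water replicate 1, 3 without water replicate 2, 1 without water replicate 3 or bromate replicate 2 and 2 without bromate replicate 3, and the count that rose 0 without water replicate 1, 2 or 3 or bromate replicate 3 and 1 without bromate replicate 1 or 2. The respiration count that fell was 1 without water replicate 1 and 0 on leaving out any 1 array other than water replicate 1, and the count that rose 0 without water replicate 2 or 3 or bromate replicate 2 or 3.

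Of 34 genes of xenobiotic metabolism 7 fell, 2 rose and 25 did not pass, with the same counts adjusted over the list alone. The carboxylesterase gene Ces1d was 3.71-fold lower (-1.89 ± 0.25) and the flavin monooxygenase genes Fmo2 2.68-fold lower (-1.42 ± 0.13) and Fmo4 2.501-fold lower (adjusted p = 0.0527 without bromate replicate 2). The 2 that rose were the cytochrome P450 gene Cyp3a9 (at least 3.84-fold) and, named after its value was seen, the glucuronosyltransferase gene Ugt2b35 (1.72-fold, adjusted p up to 0.0883 without water replicate 1 or 3 or bromate replicate 1 or 2). The median was -0.44, and -0.26 with slide as a block (camera adjusted p = 0.00403; adjusted p = 0.362 with an estimated correlation). The call ended with the straight-tubule mean, which was 4.08, 2.42 and 1.00 on the water arrays, as a covariate (adjusted p = 0.102). The count that fell was 3 without water replicate 2 or 3 and 2 without bromate replicate 2, and the count that rose 1 without water replicate 1 or 3 or bromate replicate 1 or 2.

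Genes of the unfolded protein and amino acid response and of cholesterol synthesis were higher. Of 24 members of the first list 6 rose, 0 fell and 18 did not pass (7 rose adjusted over the list alone). The asparagine synthetase gene Asns rose 5.32-fold (2.41 ± 0.12), the folate enzyme gene Mthfd2 3.62-fold (1.86 ± 0.15), Trib3 3.08-fold (adjusted p up to 0.0704 without water replicate 2 or 3 or bromate replicate 3) and Ppp1r15a 1.73-fold (adjusted p up to 0.0855 without water replicate 1, 2 or 3 or bromate replicate 3). Of 25 cholesterol genes 7 rose, 0 fell and 18 did not pass, with the same counts adjusted over the list alone. Among them the squalene epoxidase gene Sqle rose 1.75-fold (adjusted p up to 0.07 without water replicate 2 or bromate replicate 2 or 3) and Pmvk 1.67-fold (adjusted p up to 0.0655 without water replicate 2 or 3 or bromate replicate 2 or 3). Medians were 0.19 and 0.22, and 0.22 and 0.31 with slide as a block. Camera's adjusted p was 0.00111 and 0.000285 (adjusted p = 0.362 for both with an estimated correlation). The first count that rose was 3 without water replicate 1 and 2 without water replicate 2 or 3 or bromate replicate 3, and the cholesterol count 2 without water replicate 2 or bromate replicate 2 or 3 and 3 without water replicate 3.

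Extracellular matrix and fibroblast genes, interferon-stimulated genes, MHC class II genes and lysosomal genes were not called as lists (camera adjusted p = 0.259, 0.471, 0.387 and 0.471). Of 30 matrix genes 3 rose and 1 fell (4 and 1 adjusted over the list alone). The collagen genes Col18a1 and Col4a1 rose 1.71-fold (adjusted p up to 0.0676 without water replicate 2 or 3 or bromate replicate 2 or 3) and 1.35-fold (adjusted p up to 0.0994 on leaving out any 1 array other than bromate replicate 1), and Timp3 was 1.64-fold lower. Of 27 interferon-stimulated genes 2 rose and 0 fell (1 rose adjusted over the list alone), namely the transcription factor gene Irf1 (3.07-fold, 1.62 ± 0.09) and the RNA sensor gene Ifih1 (2.01-fold, adjusted p up to 0.137 on leaving out any 1 array other than bromate replicate 1). Without bromate replicate 1 both lists were called higher (adjusted p = 0.00354 and 0.00269). The matrix count that rose was 1 without water replicate 2 or 3 or bromate replicate 2 or 3 and 5 without bromate replicate 1, and the interferon count 1 on leaving out any 1 array other than bromate replicate 1 and 8 without bromate replicate 1. RT1-DMa was the 1 of 8 MHC class II genes that rose (1.51-fold, adjusted p up to 0.102 on leaving out any 1 array other than bromate replicate 3), also adjusted over the list alone. Of 30 lysosomal genes 3 rose and 2 fell, also adjusted over the list alone: the protease gene Ctsd rose 2.49-fold (1.32 ± 0.12), Scarb2 1.69-fold (adjusted p up to 0.0598 without water replicate 2 or 3) and Ctsl 1.58-fold (adjusted p up to 0.0683 without water replicate 2 or 3 or bromate replicate 2), while Glb1 (1.41-fold, adjusted p up to 0.107 on leaving out any 1 array other than water replicate 1) and, named after its value was seen, Ctsh (1.39-fold, adjusted p up to 0.128 on leaving out any 1 array other than water replicate 1) fell. The lysosomal count that rose was 1 without water replicate 2 or 3, and the count that fell 0 on leaving out any 1 array other than water replicate 1. The 4 medians were 0.14, -0.02, -0.33 and 0.05, and -0.02, -0.08, -0.39 and -0.04 with slide as a block, where the matrix and lysosomal medians thus turned sign. The interferon median was below 0 while its mean and camera's direction were above.

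Heat shock, renin-angiotensin, erythrocyte, and fat and adrenal genes were not called as lists either (camera adjusted p = 0.0864, 0.0864, 0.585 and 0.491). The small heat shock protein gene Hspb1 rose 2.99-fold (1.58 ± 0.17), 1 of 15 in its list, also adjusted over the list alone. Of 8 renin-angiotensin genes 1 rose and 2 fell, also adjusted over the list alone, with the mineralocorticoid receptor gene Nr3c2 2.14-fold lower and the angiotensin receptor gene Agtr1a 1.62-fold lower (adjusted p up to 0.101 on leaving out any 1 array other than water replicate 1). Of 9 erythrocyte genes 0 rose and 0 fell by limma, also adjusted over the list alone (0 and 0 at an unadjusted p under 0.05), and the globin gene Hba-a1 had a difference of 0.13 ± 0.24 (adjusted p = 0.736). The lipid droplet gene Cidea rose 2.81-fold, 1 of 10 in its list (1 adjusted over the list alone). The heat shock list was called without water replicate 1 (adjusted p = 0.0251), also the value with slide as a block, and without bromate replicate 3 (0.0217), and the renin-angiotensin list without water replicate 3 (0.0351) and with no filter on dim probes (0.0363). The renin-angiotensin count that fell was 1 on leaving out any 1 array other than water replicate 1 and the count that rose 0 on leaving out any 1 array other than bromate replicate 3, the heat shock count that rose 2 without bromate replicate 3, and in the fat and adrenal list 2 without water replicate 1. The 4 medians were 0.06, -0.45, 0.15 and -0.06, and 0.13, -0.22, 0.30 and 0.32 with slide as a block. The fat and adrenal median thus turned sign with slide as a block, and it was below 0 while its mean and camera's direction were above.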

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

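Among the alternatives, the model with the straight-tubule mean as a covariate was chosen after the data were seen. No called result reversed in any alternative run. Among results not called, the medians of the matrix, lysosomal, and fat and adrenal lists turned sign with slide as a block, and the differences of single genes, such as Cldn19, Ptprc and Aqp3, crossed 0 on leaving out 1 array. Of 150 genes followed singly 134 changed, and these kept their direction in every alternative, and 73 were called whichever 1 array was left out. Leaving out 1 array gave 594 to 1495 genes that rose, 530 to 1835 that fell, 406 to 628 at least 2-fold higher and 310 to 513 at least 2-fold lower. Fewer degrees of freedom go with these fits, and without water replicate 2 or bromate replicate 2 the counts were lowest. Genes that rose and fell numbered 750 and 694 with no filter on dim probes, where 45432 genes were tested, 2850 and 3396 with array weights, 614 and 516 with treat at 1.2-fold, which asks for more than a difference from 0, and 734 and 739 with the straight-tubule covariate. At least 2-fold, normexp gave 377 higher and 314 lower, against 610 and 538 in the main run. Of any size it gave 2503 and 2388, against 1891 and 2088. For array weights, normexp and the covariate the cause was not tested. Over the scalings the share of calls that rose was 47.5% to 51.2%. With an estimated correlation camera called 0 lists higher and 0 lower, against 9 and 9 at the preset. Over all alternatives, list results were the same 534 times, weaker 24 times and stronger 9 times, and single genes 2662, 453 and 10 times. The calls of Sdhb, Glb1, Gsta5, Ctsh and Anxa10 ended with quantile normalization (adjusted p up to 0.0786). Those of Pcna, Ifih1 and Ctsh ended with the percentile over probes above background on all arrays (up to 0.0544) and those of Ifih1, Glb1, Agtr1a, Ctsh, Anxa10 and S100b with normexp (up to 0.322). With the mean of a gene's probes the calls of Fen1, Pcna, Wt1, Col4a1, Ccng1 and Cd55 ended (up to 0.752). Lcn2, Nqo1 and Slc22a6 were called with array weights (up to 0.0441), and Slc7a13 with the straight-tubule covariate (0.0232). Dim signal limits the 83 and 134 changed genes given as bounds.

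With the replicate number as a block, 585 genes rose and 535 fell, and 325 were at least 2-fold lower. Deviations from the group means correlated at 0.05, 0.07 and -0.10 across genes between samples of the same number, and not every sample matched its own number best, so the numbers were not read as pairs.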

Other observations

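The tests of straight-tubule genes, of slide, of lost cells, of outer stripe tissue and of the 16 gene families were chosen after the data were seen, as were the principal and intercalated markers compared. Within the collecting duct, markers of intercalated cells, which secrete acid or base, had a lower median than those of principal cells, which take up water and sodium. Of 9 intercalated markers 8 fell and 0 rose (median -1.16), among them Foxi1, the transcription factor gene of these cells (2.11-fold lower, -1.08 ± 0.11), and the anion exchanger gene Slc4a1 (3.004-fold lower, -1.59 ± 0.21). Of 10 principal cell markers 4 fell and 0 rose (median -0.65), and the water channel gene Aqp3 had a difference of 0.03 ± 0.17 (adjusted p = 0.933). Subunit genes of the vacuolar proton pump, which overlap those markers, were also lower: 6 of 20 fell and 0 rose (median -0.24, camera adjusted p = 0.00146; adjusted p = 0.458 with an estimated correlation), among them Atp6v1c2 (4.196-fold lower) and Atp6v0d1 (1.49-fold lower, adjusted p up to 0.054 without water replicate 3 or bromate replicate 2).

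Several gene families, some of which share members with the lists, moved as well, in the same direction under quantile normalization, the other percentile and normexp. Of 69 cytosolic ribosomal protein genes 6 rose and 0 fell (median 0.19, adjusted p = 7.51e-08; adjusted p = 0.54 with an estimated correlation), and 20 rose under quantile normalization, 9 with the other percentile and 26 with normexp. Of 18 aminoacyl-tRNA synthetase genes 6 rose and 0 fell (median 0.32, adjusted p = 4.14e-05; 0.364 with an estimated correlation), such as Cars1 (1.85-fold) and Nars1 (1.74-fold), and 10, 9 and 9 rose under these scalings. Annexin genes (5 of 10 rose, 1 fell, adjusted p = 0.0244), led by Anxa2 (3.796-fold) and Anxa7 (2.54-fold), and S100 genes (5 of 13 rose, 1 fell, adjusted p = 0.0107), led by S100a10 (4.35-fold), were higher, which was not called with an estimated correlation (adjusted p = 0.364 for both). The exceptions were Anxa10, at least 1.63-fold lower (adjusted p up to 0.134 on leaving out any 1 array), and S100b, at least 1.17-fold lower (adjusted p up to 0.0874 on leaving out any 1 array other than bromate replicate 2). Of 36 proteasome genes 2 rose and 0 fell (median 0.08, adjusted p = 0.0372, and 0.68 with an estimated correlation), and 5 rose with normexp. In the main run 1891 of all 27506 genes rose, a share near that of the proteasome and ribosomal protein genes. With normexp 2503 of all genes rose and with quantile normalization 2196. Those shares were well below the 26 and 20 of 69 ribosomal protein genes that rose in these runs. Organic anion and cation carriers were lower (7 of 26 fell, median -0.75, adjusted p = 0.000289, and 0.364 with an estimated correlation), among them Slc22a25 (2.27-fold) and Slco1a4 (at least 1.58-fold, adjusted p = 0.0648 without water replicate 2), and Slco4a1 alone rose (3.54-fold). The carriers overlap the proximal and straight-tubule lists, and members such as Slco1a1 spread widely over the water arrays (SD 3.04). The other 9 families were not called by camera, claudins with the lowest adjusted p (0.0511), although the claudin gene Cldn4 rose 10.5-fold and the protease gene Mmp7 at least 5.11-fold, while the protease gene Mmp9 fell at least 3.59-fold. The genes named here and among the intercalated and principal cell markers were chosen after their values were seen.

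Genes of the straight part of the proximal tubule, which lies in the outer stripe of the outer medulla and the rays of the cortex, spread over the water arrays more than any other segment list weighed here. A difference between slides as the whole cause is argued against, since water replicates 2 and 3 shared a slide and differed by a median of 1.12 over these genes. In water replicate 1, 84.62% of the genes (11 of 13) were over 0.5 higher than in replicate 3, with a median of 2.53. Different amounts of outer stripe tissue and a difference between the animals themselves cannot be told apart by this, because the list was written after the spread was seen.

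The mean of the markers of the thick ascending limb and distal tubule, and that of the collecting duct markers, were lower in each of the 3 treated samples than in any water sample, with 25 of the 38 markers called lower. With the straight-tubule mean of each array as a covariate, the median difference of the 38 markers was -1.11 (median standard error 0.19) and 24 fell. Without the covariate it was -1.12 and 25 fell. A fall that only follows the straight-tubule genes is thus argued against. Whether their mean tracks outer stripe tissue was not tested. Little outer stripe tissue in the treated samples as the whole cause therefore cannot be decided by this. In the first list Trpv5 (3.43-fold, adjusted p up to 0.0931 on leaving out any 1 array other than water replicate 3), Kng1 (2.79-fold, adjusted p up to 0.079 without water replicate 2 or 3) and Ptger3 (1.98-fold) rose, which fewer such cells alone would not bring. For the markers that were lower, fewer such cells and a lower expression per cell cannot be told apart, because 4 of the 8 thick ascending limb markers (50%) lay over 0.5 and over 2 standard errors from the list median of -1.42, with Egf at -5.09 and Cldn19 at -0.07 as the extremes, and the other 4 lay between -1.50 and -1.38. No such test was made for the collecting duct. Potassium bromate is the difference between the groups that the design names, and the route from it to the lower markers was not settled here.

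The fibrinogen genes Fga and Fgb (differences of 3.14 and 4.65), Fgg (at least 15.02-fold) and the haemopexin gene Hpx (at least 3.72-fold), all higher under bromate, are abundant in liver. Liver RNA in the treated samples is argued against: over 15 plasma protein genes of liver, measured without a filter, the median difference was -0.15 (0.21 over the 10 that passed it), and the 95% interval of albumin ended at 0.44, below the rise of Fga. The genes of albumin and transthyretin, among the most abundant in liver, were well above background on 2 water arrays and 0 treated arrays. Which cells held these transcripts was not tested. The list was one of those written after the data were seen, and the bounds of its test were set before its result. Fga and Hpx were named after their values were seen.

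The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split was the 1 of the 10 with 3979 changed genes, 1148 of them at least 2-fold, and the other 9 gave at most 0 and 0 by limma (351 to 1232 genes at an unadjusted p under 0.05, against 9042). It was also the 1 with 18 lists called by camera at the preset correlation, and the highest of the others gave 14. The other splits each mix arrays of both treatments on both sides. Part of the treatment difference stays in them and part adds to their spread, so their counts are not those of unrelated arrays.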
